A study of Homo sapiens with 18 samples.

How the data were processed

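HT-29, an established human colorectal adenocarcinoma cell line, was grown as tumors in nude mice, and total RNA of 18 tumors was measured on Affymetrix human one-colour arrays, 1 array per tumor. Per the labels, mice entered volume-matched cohorts once their tumors measured 250 to 400 mm3. They were given gemcitabine at 60 mg/kg or vehicle, then GNE-783 at 25 mg/kg or vehicle 24 h later, and the tumors were taken another 24 h after that, 48 h after the first dose. The groups held 4 vehicle, 5 gemcitabine, 5 GNE-783 and 4 combination arrays. Each array counts as a separate animal only as far as the labels number the replicates of a group. The labels state no batch, date or genome build, so no coordinates are given.

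The deposited values are intensities of probe sets on a linear scale, from 5.76 to 27755, which the authors made with RMA in R 2.10 according to the submitters' processing notes. RMA corrects background, makes the probe distributions of the arrays equal and summarises the probes of each probe set. The plan, made before the data were examined, took the deposited values to be on the log2 scale. They were not, so their log2 was taken, with no filter and no further normalization. The table held 54662 probe sets. Of these, 41091 had a single gene symbol in the platform's table, 1801 had several and 11770 had none listed. Symbols of 41037 probe sets matched the gene reference by ID and 54 did not. Each of 19775 genes was represented by its probe set with the highest mean over all arrays, which was a choice among several probe sets for 10523 genes.

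Groups were compared with limma 3.58.1 in R 4.3.3. A single linear model with a mean per group was fitted to all 18 arrays (14 residual degrees of freedom), with moderated variances and Benjamini-Hochberg adjustment over all genes within each comparison. A gene was called changed at an adjusted p under 0.05. Changes of at least 2-fold among the called genes were counted as well. The 6 comparisons were each treatment against vehicle, the combination against each single agent, and the interaction, which is the combination minus gemcitabine less the difference between GNE-783 and vehicle. The arrays give a number of replicates, not a depth, and that number limits the precision. The procedure was tested on simulated data with 200 genes changed, drawn as independent normal noise around each gene's mean with its residual SD. It recovered 64.7 to 73.5% of log2 changes of 0.5 in the comparisons of 2 groups and 32.4% in the interaction. Recovery was at least 93.9% for log2 changes of 1, and 6 to 10 unchanged genes were called. Genes varied independently there, so these rates do not cover shifts that many genes of an array share.

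A total of 21 gene lists with 776 members were fixed before the data were examined. They cover G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, DNA repair, the replication checkpoint, p53 targets, NF-kB targets, interferon-stimulated genes, immediate early and AP-1 genes, the integrated stress and unfolded protein responses, apoptosis regulators, gemcitabine transport and nucleotide metabolism, intestinal differentiation, Wnt targets and intestinal stem cells, hypoxia and glycolysis, cholesterol synthesis, and housekeeping genes. Lists of markers covered extracellular matrix and fibroblasts, endothelium, leukocytes and macrophages, and erythroid, muscle and adipocyte cells. Lists were tested with limma's camera (two-sided, preset correlation of 0.01, adjusted over the 21 lists of a comparison), which compares the members with all other genes. It was run again with a correlation estimated per list. Members were also counted with p values adjusted over the list alone. Exact two-sided permutation tests on each list's mean per array were added after the data were seen.

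The rule for genes to name was also fixed before the data were examined. It took up to 10 of the largest rises and 10 of the largest falls among called genes whose groups' arrays did not overlap (no overlap rule for the interaction). It added up to 4 members of each list with the lowest adjusted p, up to 2 bright members that did not pass, and 15 fixed genes of the checkpoint, the cell cycle and gemcitabine metabolism. The genes named are a subset of that rule's genes, picked after the values were seen. NNMT and CFI, named for GNE-783, were added outside the rule after their values were seen.

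Alternatives were another scaling of the arrays (median subtraction or a further quantile normalization), a filter on dim genes at the 40th percentile, other choices of probe set, other variance moderation, array weights, only the compared groups in the fit, the replicate number as a block, and the mean of the extracellular matrix markers as a covariate. Each array was also left out in turn. Leaving out 2 arrays together and the interquartile range of each array as a covariate were added after the data were seen. Control probe sets for the 3' to 5' signal of ACTB and GAPDH are not used here, so the planned covariate of RNA quality was not run.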

Results

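Total RNA of 18 HT-29 tumors was compared on human expression arrays across a 2 by 2 design of vehicle (n = 4), gemcitabine (n = 5), GNE-783 (n = 5) and both agents (combination, n = 4). HT-29 is a human colorectal cancer line grown here in nude mice, gemcitabine is a nucleoside analog that interferes with DNA synthesis, and GNE-783 is an inhibitor of the checkpoint kinase CHK1. Levels are given as mean log2 intensity ± SD over arrays and changes as fold or log2 change ± SE from limma. The median deposited intensity of an array lay between 75.1 and 81.7, and correlations between arrays over 19775 genes lay between 0.9789 and 0.997. The median log2 change of all genes stayed between -0.03 and 0.02 in the 6 comparisons.

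A pair of arrays lay apart from their groups on the first principal components, which held 32.6% and 19.6% of the variance. The array labelled GNE-783 replicate 1 correlated best with gemcitabine replicate 4 (r = 0.997 across genes), and the array labelled gemcitabine replicate 2 correlated best with GNE-783 replicate 3 (r = 0.9969). The spread of levels also differed between groups. Interquartile ranges of log2 intensity were 3.26 ± 0.05 (SD, n = 4) in vehicle, 3.08 ± 0.09 (n = 5) in gemcitabine, 3 ± 0.15 (n = 5) in GNE-783 and 3.19 ± 0.1 (n = 4) in combination arrays. Against vehicle the exact permutation p was 0.0159 for gemcitabine and for GNE-783 (0.125 adjusted) and 0.371 for the combination. In GNE-783 arrays the brightest 10% of genes had a median log2 change of -0.18, and dimmer genes had medians up to 0.11. Gemcitabine arrays showed a smaller tilt of the same kind, from -0.11 for the brightest 10% to 0.1, and combination arrays from -0.07 to 0.04.

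**Figure D1:**
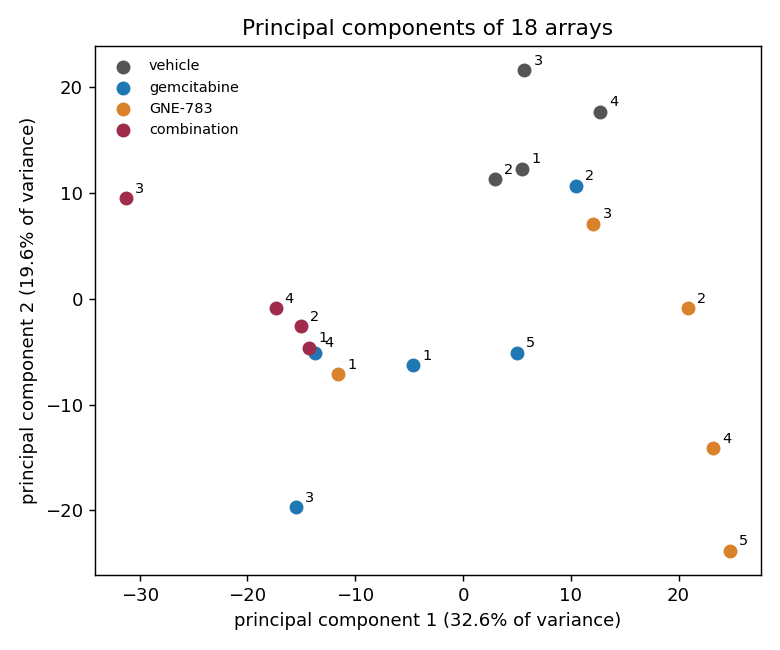
Each point is an array, placed by its scores on the first (32.6% of variance) and second (19.6%) principal component of log2 intensity and numbered by replicate within its group. The array labelled GNE-783 replicate 1 sits at -11.6 and -7.1 among gemcitabine and combination arrays, and gemcitabine replicate 2 sits at 10.5 and 10.7.

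The combination was compared with vehicle to ask what gemcitabine followed by the CHK1 inhibitor changed in the tumors. Higher were 36 of 50 interferon-stimulated genes, 15 of 34 NF-kB targets and 24 of 64 mitotic genes, with none lower. These lists passed camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.31, adjusted p = 0.13 and adjusted p = 0.38). CCL20, a chemokine that attracts CCR6-bearing lymphocytes, was 4.59-fold higher (9.32 ± 0.79 against 7.12 ± 0.45, SD, n = 4 each, adjusted p = 0.00052), and S100A2, an epithelial calcium-binding protein, was 5.21-fold higher (11.09 ± 0.31 against 8.71 ± 0.1, adjusted p = 0.0038). IFIT1, an antiviral protein that binds RNA, was 3.12-fold higher (10.59 ± 0.3 against 8.95 ± 0.26), CDK1, the kinase that drives entry into mitosis, 2.32-fold higher (11.44 ± 0.44 against 10.23 ± 0.15), and CDKN1A, the p53-induced CDK inhibitor p21, 2.71-fold higher (11.14 ± 0.18 against 9.71 ± 0.17). Arrays of the combination and of vehicle did not overlap for any of these 5 genes. The rule for the largest rises required this, so it adds no support for genes named by it. With gemcitabine alone, S100A2 lay at 10.59, 8.78, 10.98, 10.62 and 9.16 in replicates 1 to 5, without passing the test. In all, 1851 genes passed, 806 higher and 1045 lower. Of these, 66 rose and 13 fell by at least 2-fold, and over all 19775 genes the groups' arrays did not overlap for 3807, where chance gives 2.857%.

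Among the interferon-stimulated genes, 36 of 50 rose and none fell (48 rose when adjusted over the list alone), with a median log2 change of 1.01 (camera adjusted p = 3.7e-27, and adjusted p = 0.31 with an estimated correlation). IFI44 was 3.32-fold higher, OAS3, which makes the activator of RNase L, 3.17-fold, IFITM1, which restricts viral entry, 2.49-fold, and DHX58, a sensor of viral RNA, 1.74-fold. The list's mean per array was 9.68 ± 0.14 against 8.69 ± 0.28 (n = 4 each), higher in all 4 combination arrays (exact permutation p = 0.0286, the smallest for these groups, and 0.0545 adjusted). Of 34 NF-kB targets, 15 rose and none fell (20 over the list alone), with a median of 0.34 (camera adjusted p = 5e-11, and adjusted p = 0.13 with an estimated correlation). CXCL8, the neutrophil chemokine, was 2.87-fold higher and IER3, a stress-induced regulator of survival, 1.77-fold. HCP5, a long noncoding RNA of the HLA region, was 3.12-fold higher and APOBEC3B, a DNA cytidine deaminase, 3.5-fold higher. APOBEC3B lay at 8.94, 7.59, 9.39, 9.66 and 8.23 in gemcitabine replicates 1 to 5, and at 7.48 to 7.83 in vehicle arrays. Leukocyte and macrophage markers, measured beside these lists, had a median log2 change of -0.01 and a mean of 0.05 (camera adjusted p = 0.36, direction up). LAPTM5 (1.73-fold), a lysosomal protein of blood cells, and CD74 (1.58-fold), the invariant chain of MHC class II, were among the 3 of 23 markers that rose. LYZ (lysozyme), the brightest marker, was 12.95 ± 0.27 against 13.05 ± 0.07. CD74 has 2 further, dimmer probe sets, at 0.01 and -0.1.

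Of 64 G2/M and mitosis genes, 24 rose and none fell (35 over the list alone), with a median log2 change of 0.43 (camera adjusted p = 2.3e-16, and adjusted p = 0.38 with an estimated correlation). UBE2C, which directs cyclin destruction at anaphase, was 1.88-fold higher, TOP2A, the topoisomerase that untangles chromosomes, 1.81-fold, the proliferation antigen MKI67 1.65-fold (dimmer probe sets 0.72, 0.04 and 0.29 on the log2 scale) and cyclin B1 (CCNB1) 1.54-fold. G1/S and replication genes had a median of 0.26, with 1 of 55 up and 2 down (0 and 2 over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.7 with an estimated correlation). The 2 that fell were UNG, which removes uracil from DNA (log2 change -0.54 ± 0.1), and MCM6, a subunit of the replicative helicase (-0.59 ± 0.13). DNA repair genes had 1 up and 1 down of 44 (6 and 2 over the list alone, median 0.24, camera adjusted p = 0.0015, and adjusted p = 0.6 with an estimated correlation). Replication checkpoint genes had 1 up and 2 down of 23 (4 and 3 over the list alone, median 0.33, camera adjusted p = 0.041, and adjusted p = 0.58 with an estimated correlation).

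Of 46 p53 targets, 10 rose and 1 fell (12 and 2 over the list alone), with a median log2 change of 0.1 (camera adjusted p = 0.0013, and adjusted p = 0.38 with an estimated correlation). GDF15, a secreted stress cytokine, was 2.74-fold higher, and the death receptor FAS 1.87-fold. Apoptosis regulators had 4 of 33 up and none down (5 over the list alone, median 0.14, camera adjusted p = 0.00058, and adjusted p = 0.39 with an estimated correlation). They included PMAIP1 (NOXA, 1.7-fold) and BIK (1.56-fold), which both promote cell death through the mitochondria. Immediate early and AP-1 genes had 7 of 34 up and none down (11 up and 1 down over the list alone, median 0.17, camera adjusted p = 0.00034, and adjusted p = 0.39 with an estimated correlation). Integrated stress and unfolded protein response genes had 2 up and 1 down of 36, the same numbers over the list alone (camera adjusted p = 0.48).

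The genes that fell included 7 of 18 cholesterol synthesis genes (8 over the list alone), with none up and a median log2 change of -0.22 (camera adjusted p = 1.7e-06, and adjusted p = 0.3 with an estimated correlation). INSIG1, a sterol-regulated anchor of the SREBP pathway, changed by -0.95 ± 0.17 and DHCR7, the last enzyme of cholesterol synthesis, by -0.62 ± 0.1. Of 33 genes of gemcitabine transport and nucleotide metabolism, 2 rose and 6 fell (4 and 8 over the list alone), and the median (-0.03), the mean (0.02) and the camera direction (down, adjusted p = 0.48) differed in sign. DUT, which degrades dUTP, changed by -0.55 ± 0.08. H2AC6, a histone H2A gene, was 2.1-fold lower. TRIM2 (2.18-fold), a ubiquitin ligase, PLA2G4A (2.19-fold), which releases arachidonic acid, TPPP3 (2.29-fold), a tubulin-binding protein, and CFI (2.46-fold), a complement inhibitor, were also lower. The fold of CFI leaned on vehicle replicate 3 (7.92, against 5.45, 6.32 and 5.84 in vehicle 1, 2 and 4), but the call held without this array. Dimmer probe sets of TRIM2 changed by -0.92 to 0.13. HBE1, embryonic globin, fell further than the genes named above, to 8.43 ± 0.73 against 11.45 ± 0.38 (adjusted p = 0.046), but its dimmer probe set changed by -0.13. Quantile normalization, trend and robust moderation, the matrix and interquartile range covariates, and leaving out any vehicle or combination array each ended this call. Other large rises were GPX3 (3.42-fold), a secreted peroxidase, ECM1 (3.35-fold), a matrix protein, and AQP3 (3.07-fold), a water and glycerol channel, whose dimmer probe sets changed by 0.74 and 0.64 (log2) against 1.62. HBE1, GPX3 and ECM1 did not pass with gemcitabine alone. In gemcitabine replicates 1 to 5, HBE1 lay at 7.92, 10.61, 7.03, 8.44 and 10.67. GPX3 lay at 10.13, 8.42, 10.46, 10.45 and 9.27 there (vehicle 8.31 to 8.95). ECM1 lay at 9.52, 8.22, 9.76, 9.51 and 8.37 (vehicle 7.94 to 8.28).

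Endothelial markers averaged 6.44 ± 0.03 in combination and 6.33 ± 0.03 in vehicle arrays (exact permutation p = 0.0286, adjusted 0.0545). Of 16 markers 2 rose, also over the list alone, among them ESAM, a junction protein (1.59-fold), with a median of 0.08 (camera adjusted p = 0.13). None of 25 extracellular matrix and fibroblast markers passed (median -0.02, mean -0.05, camera adjusted p = 0.74), and 3 of 20 erythroid, muscle and adipocyte markers rose (median 0.08, camera adjusted p = 0.14). With each array's median subtracted, 619 genes rose and 1344 fell. Leaving out single arrays gave 938 to 2196 genes, with 1199 without vehicle replicate 1, 1046 without vehicle 3, 938 without vehicle 4, and 1060, 1084 and 1202 without combination 2, 3 and 4. These 6 arrays, left out singly, each ended the calls of MKI67 and CCNB1, and some ended those of GDF15, PMAIP1 and ESAM, while the mean of all probe sets ended those of MKI67, CD74 and CFI and median subtraction that of CCNB1. The camera call of the replication checkpoint list ended with the matrix covariate and without probe sets shared between transcripts.

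**Figure D2:**
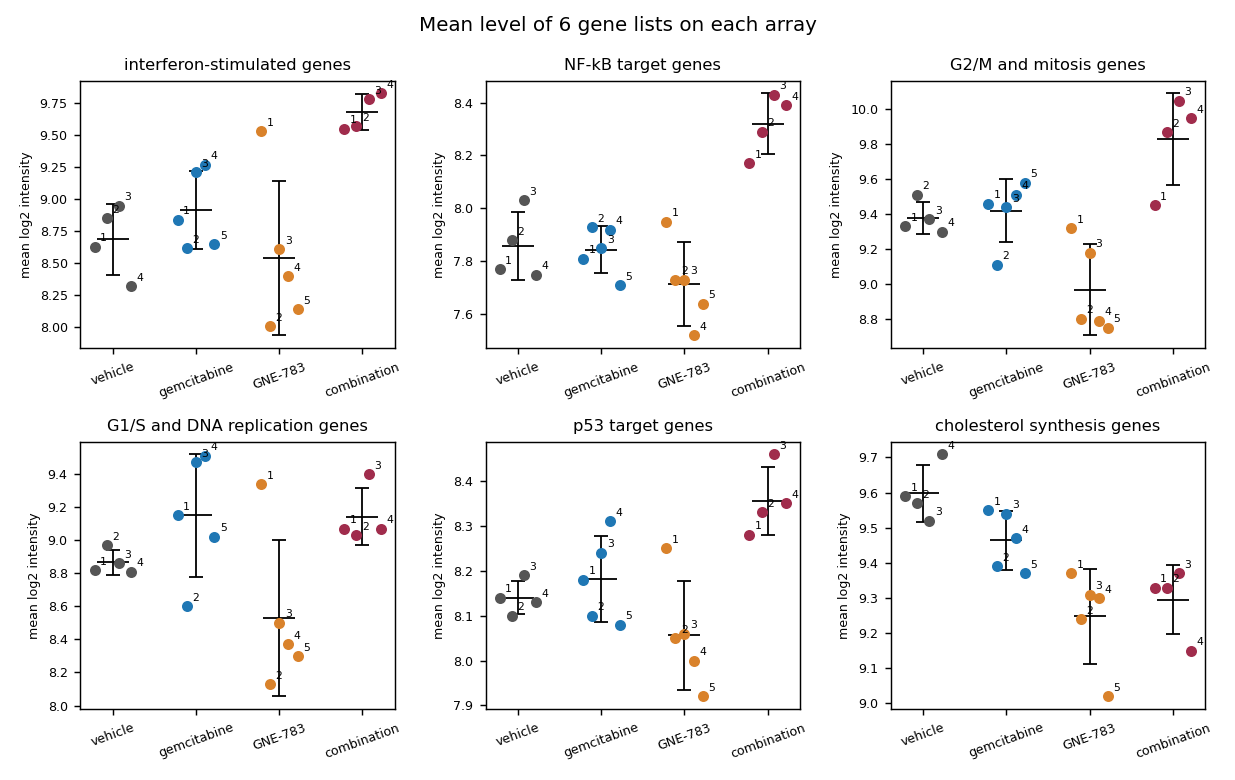
Each point is the mean log2 intensity of a gene list in an array, numbered by replicate, for interferon, NF-kB, G2/M, G1/S, p53 and cholesterol lists in 4 treatment groups, with bars for the group mean ± SD. The interferon list averaged 9.68 ± 0.14 in combination and 8.69 ± 0.28 in vehicle arrays, and the cholesterol list 9.29 ± 0.1 and 9.6 ± 0.08.

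GNE-783 was compared with vehicle to ask what the CHK1 inhibitor changed alone, 24 h after its dose. The test passed 1248 genes, 664 higher and 584 lower. Lower were 12 of 64 mitotic and 9 of 18 cholesterol synthesis genes, with none higher (adjusted p = 0.41 and adjusted p = 0.17 with an estimated correlation). MMP7, a matrix metalloproteinase of intestinal epithelium, was 2.1-fold lower (10.92 ± 0.38, n = 5, against 11.99 ± 0.29, n = 4, adjusted p = 0.014), and AURKA, a mitotic kinase, 1.66-fold lower (9.43 ± 0.23 against 10.17 ± 0.09, adjusted p = 0.037). IL33, an alarmin cytokine, was 1.83-fold higher (7 ± 0.33 against 6.12 ± 0.19, adjusted p = 0.0096) and AQP3 1.76-fold higher (10.2 ± 0.25 against 9.38 ± 0.48, adjusted p = 0.027), with no overlap between the arrays of the groups for these 4 genes. The rule for the largest rises and falls required this, so it adds no support for genes named by it. For AQP3 the lowest GNE-783 array and the highest vehicle array both lay at 9.92 after rounding. Dimmer probe sets of AQP3 changed by 0.39 and 0.42 against 0.82. MMP7, NNMT, an enzyme that methylates nicotinamide, and CFI were the 3 genes past 2-fold, all lower. NNMT was 2.51-fold and CFI 2.11-fold lower, with overlapping arrays, and other probe sets of these genes changed by -0.95 and 0.12 for NNMT and by -0.24 for CFI. CFI lay at 5.45, 6.32, 7.92 and 5.84 in vehicle replicates 1 to 4, so its fold leaned on vehicle 3. Leaving out vehicle 2, vehicle 3, GNE-783 4 or GNE-783 5 ended the calls of both NNMT and CFI. Over all 19775 genes the groups' arrays did not overlap for 2401, where chance gives 1.587%. GNE-783 arrays also had the narrowest spread of levels, an interquartile range of 3 ± 0.15 against 3.26 ± 0.05.

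Of 64 G2/M and mitosis genes 12 fell and none rose (36 fell and 1 rose over the list alone), with a median log2 change of -0.4 (camera adjusted p = 2.5e-14, and adjusted p = 0.41 with an estimated correlation). BIRC5 (survivin) changed by -0.6 ± 0.14, the spindle checkpoint kinase BUB1 by -0.56 ± 0.13, the kinetochore protein CENPF by -0.54 ± 0.13 and the mitotic kinesin KIF14 by -0.64 ± 0.16. Dimmer probe sets of BIRC5 changed by 0.04, -0.23 and -0.31 and of CENPF by -0.32 and -0.34. G1/S and replication genes had 3 of 55 down and none up, also over the list alone (median -0.38, camera adjusted p = 1.8e-06, and adjusted p = 0.51 with an estimated correlation). The list's mean per array was 9.34 in GNE-783 replicate 1 and 8.13 to 8.5 in the others. Its difference from vehicle was -0.34 (exact permutation p = 0.214), and -0.54 without both arrays that lay apart (p = 0.0286). The called members are given next. The 3 that fell were MCM5 (-0.7 ± 0.19), MCM6 (-0.57 ± 0.13) and UNG (-0.41 ± 0.09), and a dimmer probe set of MCM5 changed by -0.32. CHEK1, the gene of the drug's target, did not pass (7.77 ± 0.44 against 8.07 ± 0.15), nor did WEE1, a kinase that restrains CDK1 (10.32 ± 0.32 against 10.19 ± 0.18). Interferon-stimulated genes averaged 8.54 ± 0.6 against 8.69 ± 0.28, and none of 50 passed. Their median log2 change was -0.17 (camera adjusted p = 0.093, and adjusted p = 0.8 with an estimated correlation). Without both arrays that lay apart it was -0.398, and the list then passed camera with the preset correlation (adjusted p = 2.95e-08). The exact permutation p on the list's mean per array was 0.114 in that setting.

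Cholesterol synthesis genes had 9 of 18 down and none up (13 over the list alone), with a median log2 change of -0.37 (camera adjusted p = 9e-08, and adjusted p = 0.17 with an estimated correlation). The list's mean per array was 9.25 ± 0.14 (n = 5) against 9.6 ± 0.08 (n = 4), lower in all 5 GNE-783 arrays (exact permutation p = 0.00794, the smallest for these groups, and 0.167 adjusted). FDPS, which makes farnesyl diphosphate, changed by -0.64 ± 0.12, HMGCS1, an early enzyme of the pathway, by -0.5 ± 0.12, EBP, a sterol isomerase, by -0.52 ± 0.12 and DHCR7 by -0.5 ± 0.1. Dimmer probe sets changed by -0.14 for HMGCS1 and by -0.57, -0.27 and 0.08 for EBP. SCD, the stearoyl-CoA desaturase, changed by -0.69 ± 0.13 on its brightest probe set, and its dimmer probe sets by -0.2, 0.1 and 0.08. LRP8, a lipoprotein receptor, was 1.61-fold lower. Of 33 genes of nucleotide metabolism 4 fell and none rose (7 down and 1 up over the list alone, median -0.2, camera adjusted p = 0.00089, and adjusted p = 0.17 with an estimated correlation), among them DUT (-0.46 ± 0.07) and NME1, a nucleoside diphosphate kinase (-0.5 ± 0.11). Other falls were SLC6A14, a dim gene of an amino acid transporter (1.66-fold), KITLG, the ligand of the KIT receptor (1.74-fold), SPINK1, a trypsin inhibitor (1.73-fold), and the serine protease KLK6 (1.72-fold). Rises included SELENOP, a selenium carrier (1.58-fold), CNTFR, a cytokine receptor subunit (1.51-fold), and CDX1, an intestinal transcription factor (1.27-fold).

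Of the markers of other cells, THY1 (0.34 ± 0.08) and COL6A1 (0.33 ± 0.09) rose among 25 extracellular matrix and fibroblast markers, and VWF (0.29 ± 0.09) among 16 endothelial markers. Endothelial markers averaged 6.4 ± 0.06 against 6.33 ± 0.03 (exact permutation p = 0.0476, adjusted 0.2). Leukocyte markers had 1 of 23 up (median 0.13, camera adjusted p = 0.026, and adjusted p = 0.41 with an estimated correlation), and erythroid, muscle and adipocyte markers 3 of 20 (median 0.12, camera adjusted p = 0.0052, and adjusted p = 0.17 with an estimated correlation). Below the median level of all genes lay 545 of the 664 rises, and above it lay 543 of the 584 falls. After a further quantile normalization 130 genes rose and 45 fell, and 159 of the 1248 calls remained, with 11 of the 31 called genes named here. Those that remained were IL33, AQP3, CNTFR, CDX1, MMP7, KITLG, SPINK1, KLK6, SLC6A14, DUT and FDPS. It also ended the camera calls of the nucleotide metabolism (median -0.124), leukocyte (0.069) and erythroid, muscle and adipocyte lists (0.083), as did the interquartile range covariate. The filter on dim genes also ended the first of these calls, and other choices of probe set the other ones. With medians subtracted, 556 rose and 812 fell. With the interquartile range as a covariate limma passed none (1223 at an unadjusted p under 0.05). Every GNE-783 array had a narrower range (2.81 to 3.16) than any vehicle array (3.22 to 3.32). The covariate thus takes up most of a treatment change too, and cannot separate spread from treatment. Single arrays left out gave 541, 86, 72 and 480 genes without vehicle 1 to 4, and 2208, 720, 2522, 94 and 92 without GNE-783 1 to 5.

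Gemcitabine was compared with vehicle to ask what the nucleoside analog changed alone, 48 h after its dose. The test passed 9 genes, 5 higher and 4 lower. TTR, a carrier of thyroid hormone and retinol, was 1.67-fold higher (9.31 ± 0.3, n = 5, against 8.57 ± 0.09, n = 4, adjusted p = 0.036), and CYP2B6, a drug-metabolising cytochrome P450, 1.61-fold higher (7.73 ± 0.21 against 7.04 ± 0.13, adjusted p = 0.013). SLC6A14 changed by -1 ± 0.13 on the log2 scale, just short of 2-fold (3.81 ± 0.2 against 4.81 ± 0.28, adjusted p = 0.0026). It is a dim gene, with both means below the lower quartile of every array (5.56 to 5.8). The filter on dim genes left 6 of the 9 called genes in the test, and 5 of these still passed, all but CEP290. The other rises were UGT2B28, a glucuronosyltransferase (1.42-fold), ADGRB2, an adhesion receptor (1.38-fold), and APOA2, an apolipoprotein (1.35-fold). The other falls were CNDP2, a dipeptidase (-0.59 ± 0.09), ZNF717, a zinc finger protein (-0.53 ± 0.09), and CEP290, a ciliary protein (-0.46 ± 0.08). Most of these genes also lay to the same side of vehicle with GNE-783 alone, so they do not set gemcitabine apart. GNE-783 arrays lay at 8.77 to 9.41 for TTR (vehicle 8.48 to 8.68) and 7.45 to 7.75 for CYP2B6 (6.93 to 7.22). They lay at 3.94 to 4.33 for SLC6A14 (4.54 to 5.15) and 9.46 to 9.67 for CNDP2 (9.91 to 10.27). ZNF717 overlapped vehicle (7.2 to 7.62 against 7.49 to 7.84). Without probe sets shared between transcripts the changes of CNDP2 and CEP290 turned to 0.169 and 0.291. Over all 19775 genes the arrays did not overlap for 1571, where chance gives 1.587%. limma passed none at 2-fold, and 4233 genes had an unadjusted p under 0.05.

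None of 15 genes named in advance passed with gemcitabine. CDKN1A was 10.23 ± 0.71 (n = 5) against 9.71 ± 0.17 (n = 4), RRM2, a subunit of the ribonucleotide reductase that gemcitabine inhibits, 11.69 ± 0.75 against 11.12 ± 0.12, and cyclin E2 (CCNE2) 8.32 ± 0.93 against 7.76 ± 0.11. TYMS, thymidylate synthase, was 11.79 ± 0.49 against 11.43 ± 0.11, CHEK1 8.3 ± 0.33 against 8.07 ± 0.15, and GDF15 9.12 ± 0.64 against 8.9 ± 0.52. G1/S and replication genes had a median log2 change of 0.29, with 52 of 55 higher but none past the test, also over the list alone (camera adjusted p = 0.00013, and adjusted p = 0.86 with an estimated correlation). Interferon-stimulated genes had a median of 0.2 (camera adjusted p = 0.027, and adjusted p = 0.86 with an estimated correlation) and DNA repair genes 0.18 (camera adjusted p = 0.037, and adjusted p = 0.86 with an estimated correlation), with none past the test. Of 33 genes of gemcitabine transport and nucleotide metabolism none passed over all genes and 2 were lower over the list alone (median -0.07, mean -0.01, camera adjusted p = 0.17, direction down). Integrated stress and unfolded protein response genes had none past the test over all genes and 8 of 36 lower over the list alone (median -0.31, camera adjusted p = 7.9e-10, and adjusted p = 0.59 with an estimated correlation). HSPA5, the chaperone BiP, was 11.67 ± 0.25 against 11.95 ± 0.28, and CEBPB, a stress-induced transcription factor, 11.53 ± 0.2 against 11.74 ± 0.15. Endothelial markers averaged 6.44 ± 0.05 against 6.33 ± 0.03 (exact permutation p = 0.0159, adjusted 0.233).

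The count rested on single arrays. It was 1104 without gemcitabine replicate 2, which lay apart, and 1820 (830 higher, 990 lower) without it and GNE-783 replicate 1, with all 9 genes kept. RRM2 and TYMS then passed, with log2 changes of 0.83 and 0.54. It was 4, 1, 1 and 2 without vehicle 1 to 4, 4, 1 and 1 without gemcitabine 1, 3 and 4, and 4, 3 and 3 without combination 1, 2 and 4. Median subtraction gave 3 rises and 12 falls and quantile normalization 2 rises and 3 falls, and limma fitted to these arrays alone passed none (4576 at an unadjusted p under 0.05). With the extracellular matrix covariate the dim gene SLC6A14 alone of the 9 passed, and with the interquartile range none did. Every gemcitabine array had a narrower range (2.95 to 3.2) than any vehicle array (3.22 to 3.32), so that covariate cannot separate spread from treatment. The camera calls of the interferon and DNA repair lists ended with other choices of probe set.

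The combination was compared with gemcitabine to ask what GNE-783 added to it. Of 34 NF-kB targets 5 rose and none fell, a list call that held with an estimated correlation (adjusted p = 0.011). CCL20 was 4.53-fold higher (9.32 ± 0.79, n = 4, against 7.14 ± 0.27, n = 5, adjusted p = 0.0017), CXCL3, another neutrophil chemokine, 2.39-fold higher (7.38 ± 0.36 against 6.12 ± 0.31, adjusted p = 0.0017) and CXCL8 2.59-fold higher (10.56 ± 0.34 against 9.18 ± 0.37, adjusted p = 0.041). The test passed 46 genes, 38 higher and 8 lower, and 6 rose by at least 2-fold. The remaining 3 of these 6 were HCP5 (2.54-fold), TRIM31, a ubiquitin ligase (2.03-fold), and TUBB2A, a beta tubulin (2.03-fold). The arrays of these groups did not overlap for 1006 of 19775 genes, where chance gives 1.587%.

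Of 34 NF-kB targets 5 rose and none fell (22 rose and 1 fell over the list alone), with a median log2 change of 0.4 (camera adjusted p = 1e-20). This call held with an estimated correlation (adjusted p = 0.011), and the list's mean per array was 8.32 ± 0.11 (n = 4) against 7.84 ± 0.09 (n = 5), higher in all 4 arrays (exact permutation p = 0.00794, adjusted 0.0833). IER3 was 1.63-fold higher. Interferon-stimulated genes had 1 of 50 up over all genes, SAMD9L, an antiviral protein (1.77-fold), and 46 up over the list alone (median 0.8, camera adjusted p = 1.1e-35, and adjusted p = 0.11 with an estimated correlation). SLFN5, of an interferon-inducible family outside the list, was 1.94-fold higher. G2/M genes had 2 of 64 up, UBE2C (1.77-fold) and PTTG1, securin (1.66-fold), and 36 over the list alone (median 0.42, camera adjusted p = 2.5e-29, and adjusted p = 0.11 with an estimated correlation). G1/S genes had a median of -0.01, with none past the test. Without both arrays that lay apart their median was -0.149, and the list was called lower by camera with the preset correlation (adjusted p = 9.74e-05). CCNB1 was 10.55 ± 0.48 against 9.8 ± 0.29, and did not pass.

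Of 36 integrated stress and unfolded protein response genes 2 rose and none fell (5 over the list alone, median 0.25, camera adjusted p = 2.3e-10, and adjusted p = 0.18 with an estimated correlation), CEBPB (1.57-fold) and ATF5, a transcription factor of the stress response (1.47-fold), of which 2 dimmer probe sets changed by 0.06 and -0.01. Apoptosis regulators also had 2 of 33 up and none down (7 over the list alone, median 0.18, camera adjusted p = 6.9e-10, and adjusted p = 0.11 with an estimated correlation), PMAIP1 (1.84-fold) and BIK (1.44-fold). None of 46 p53 targets passed over all genes (9 up and 1 down over the list alone, camera adjusted p = 3.7e-05, and adjusted p = 0.13 with an estimated correlation). CDKN1A was 11.14 ± 0.18 against 10.23 ± 0.71 and GDF15 10.35 ± 0.17 against 9.12 ± 0.64. SERTAD1, a cofactor of CDK4 and E2F (1.93-fold), and CDKN2B, the CDK inhibitor p15 (1.83-fold), rose. The falls included SCD (-0.62 ± 0.13) and ACACA (-0.46 ± 0.09), enzymes of fatty acid synthesis, MMAB, an enzyme of vitamin B12 metabolism (-0.49 ± 0.1), PLD1, a phospholipase (-0.45 ± 0.09), and the noncoding RNAs HOTTIP (-0.5 ± 0.1) and GATA6-AS1 (-0.52 ± 0.1). Dimmer probe sets of SCD changed by -0.33, -0.01 and -0.08. Cholesterol synthesis genes had a median of -0.14 with none past the test and 4 of 18 lower over the list alone (camera adjusted p = 0.00031, and adjusted p = 0.23 with an estimated correlation).

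The count of 46 was 3 without combination replicate 3, 126 without GNE-783 1 and 110 without combination 1. It was 16, 29 and 21 without vehicle 1 to 3, 4, 27, 25 and 20 without gemcitabine 1, 2, 4 and 5, 29 and 21 without GNE-783 2 and 3, and 6 and 5 without combination 2 and 4. With the extracellular matrix marker mean as a covariate 2 genes passed, and with the interquartile range 3 did. Each covariate ended the calls of CXCL8, HCP5, TRIM31, TUBB2A, PMAIP1, SLFN5 and most other named genes, as did leaving out gemcitabine 1 or combination 2, 3 or 4. CCL20 passed in all of these. Trend and robust moderation ended the calls of CXCL8, HCP5, TUBB2A, PMAIP1 and SAMD9L. Quantile normalization gave 36 rises and 18 falls, and without both arrays that lay apart 84 rose and 22 fell. Extracellular matrix markers averaged 7.09 ± 0.12 in the combination (n = 4) and 7.25 ± 0.08 in gemcitabine arrays (n = 5, exact permutation p = 0.0635, adjusted 0.148), with none of 25 past the test (camera adjusted p = 0.0046, and adjusted p = 0.3 with an estimated correlation), a call that the filter on dim genes ended.

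The combination was compared with GNE-783 to ask what gemcitabine changed in animals that also received the CHK1 inhibitor. The test passed 2243 genes, 1795 higher and 448 lower. Higher were 47 of 50 interferon-stimulated genes, 60 of 64 mitotic and 25 of 55 replication genes, with none lower (adjusted p = 0.12, adjusted p = 0.083 and adjusted p = 0.27 with an estimated correlation). NF-kB targets had 21 of 34 higher (adjusted p = 0.047 with an estimated correlation). CCL20 was 4.84-fold higher (9.32 ± 0.79, n = 4, against 7.04 ± 0.44, n = 5, adjusted p = 0.00041), CXCL8 4-fold higher (10.56 ± 0.34 against 8.56 ± 0.69, adjusted p = 0.00044) and S100A2 4.82-fold higher (11.09 ± 0.31 against 8.82 ± 1.02, adjusted p = 0.003). KIF2C, a mitotic kinesin, was 2.55-fold higher (10.47 ± 0.19 against 9.12 ± 0.43, adjusted p = 0.00044). At least 2-fold changes were seen for 138 rises and 1 fall, that of DEPTOR, an inhibitor of mTOR (2.29-fold). The arrays of these groups did not overlap for 1684 of 19775 genes, where chance gives 1.587%.

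Of 64 G2/M genes 60 rose and none fell (62 over the list alone), with a median log2 change of 0.88 (camera adjusted p = 2.1e-45, and adjusted p = 0.083 with an estimated correlation). UBE2C was 2.38-fold, CCNB1 2.2-fold, BIRC5 2.1-fold and MKI67 2.09-fold higher, with log2 changes of 0.42 to 0.6 for dimmer probe sets of BIRC5 and 0.53 to 1.13 for those of MKI67. G1/S and replication genes had 25 of 55 up and none down (41 over the list alone, median 0.63, camera adjusted p = 1.9e-15, and adjusted p = 0.27 with an estimated correlation), among them TK1, thymidine kinase (2.35-fold), and FEN1, which trims Okazaki fragments (2.03-fold). DNA repair genes had 18 up and 1 down of 44 (31 and 1 over the list alone, median 0.35, camera adjusted p = 3e-11, and adjusted p = 0.2 with an estimated correlation), among them the helicase BLM (2-fold). Replication checkpoint genes had 13 of 23 up and none down, also over the list alone (median 0.52, camera adjusted p = 2.7e-06, and adjusted p = 0.17 with an estimated correlation). MDC1, which marks DNA breaks, was 1.9-fold, CHEK1 1.63-fold and CHEK2 1.44-fold higher, but dimmer probe sets of CHEK1 changed by 0.46, 0.84 and -0.18. Nucleotide metabolism genes had 9 of 33 up and none down (9 up and 1 down over the list alone, median 0.11, camera adjusted p = 0.025, and adjusted p = 0.22 with an estimated correlation). SAMHD1, which degrades dNTPs, was 2.15-fold, RRM2 2.28-fold, RRM1 1.76-fold and TYMS 1.71-fold higher, and quantile normalization ended the calls of RRM1, RRM2 and TYMS and of the nucleotide metabolism list (median 0.062), which the filter on dim genes, the interquartile range covariate and leaving out shared probe sets also ended.

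Interferon-stimulated genes had 47 of 50 up and none down (49 over the list alone, median 1.19, camera adjusted p = 1.4e-33, and adjusted p = 0.12 with an estimated correlation). IFIT1 was 3.62-fold, OAS3 3.58-fold, IFI44 3.51-fold and BST2, which tethers virions, 2.07-fold higher. The array labelled GNE-783 replicate 1 was the highest of its group for BST2 (10.73 against a mean of 9.57). NF-kB targets had 21 of 34 up and none down (25 over the list alone, median 0.53, camera adjusted p = 7.6e-15), a call that held with an estimated correlation (adjusted p = 0.047). PI3, the elastase inhibitor elafin (3.29-fold), and ULBP2, a ligand of the NK cell receptor NKG2D (3.55-fold), also rose. Of 46 p53 targets 15 rose and none fell (16 over the list alone, median 0.22, camera adjusted p = 2.4e-06, and adjusted p = 0.11 with an estimated correlation), with CDKN1A 3.01-fold higher. Apoptosis regulators had 13 of 33 up and none down (17 over the list alone, median 0.27, camera adjusted p = 1.2e-09, and adjusted p = 0.11 with an estimated correlation). MCL1, which opposes cell death, was 1.51-fold and PMAIP1, which antagonises it, 2.03-fold higher. Cholesterol synthesis genes had 2 of 18 up, with a median (-0.02) below and a mean (0.05) above 0 (camera adjusted p = 0.66, direction up). Among the falls were H2AC6 (-0.92 ± 0.21), TRIM2 (-0.83 ± 0.17) and TPPP3 (-0.77 ± 0.17). Dimmer probe sets of TRIM2 changed by -0.81 to -0.11.

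Quantile normalization gave 1180 rises and 855 falls and kept 1434 of the calls, and with the interquartile range as a covariate 57 genes passed, with 5 of the 31 called genes named here. Without both arrays that lay apart 2607 rose and 1005 fell, with 2211 of the calls kept. Single arrays moved the count to 745 without combination replicate 3, 3377 without GNE-783 1, 1128 without GNE-783 4 and 1287 without GNE-783 5. Only the arrays of these groups in the fit gave 1273, and the extracellular matrix covariate 1337.

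**Figure D3:**
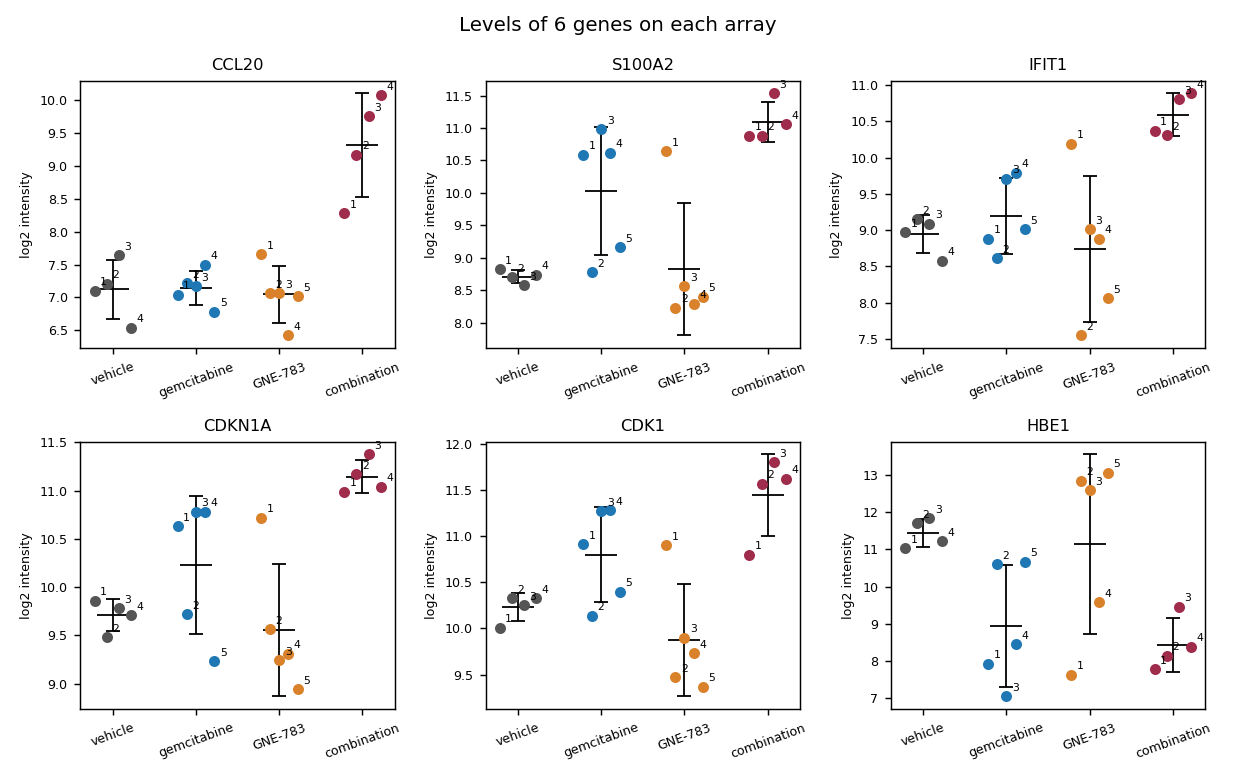
Each point is the log2 intensity of a gene in an array, numbered by replicate, for CCL20, S100A2, IFIT1, CDKN1A, CDK1 and HBE1 in 4 treatment groups, with bars for the group mean ± SD. CCL20 averaged 9.32 ± 0.79 in combination arrays and 7.04 ± 0.44 to 7.14 ± 0.27 in the other groups.

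The interaction asked whether the combination departed from the sum of the single-agent changes on the log2 scale. Above the sum lay 14 of 34 NF-kB targets and 32 of 64 mitotic genes (adjusted p = 0.19 and adjusted p = 0.22 with an estimated correlation). CCL20 exceeded it by 2.26 ± 0.4 (log2 ± SE, adjusted p = 0.018), with group means of 7.12 ± 0.45 in vehicle (n = 4), 7.14 ± 0.27 in gemcitabine (n = 5), 7.04 ± 0.44 in GNE-783 (n = 5) and 9.32 ± 0.79 in combination arrays (n = 4). CXCL8 exceeded it by 1.85 ± 0.38 (adjusted p = 0.024), PI3 by 1.91 ± 0.45 (adjusted p = 0.032) and NNMT by 2.07 ± 0.41 (adjusted p = 0.024). NNMT was about level between combination and vehicle (9.32 ± 0.13 against 9.38 ± 0.88). It averaged 8.05 ± 0.52 with GNE-783 and 8.576 ± 0.284 with gemcitabine alone (n = 5 each), and only the first differed from vehicle by the test. The test passed 765 genes, 358 above and 407 below the sum, and 43 departed by at least 2-fold, all above it.

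Of 34 NF-kB targets 14 lay above the sum and none below (20 above and 1 below over the list alone, median 0.58, camera adjusted p = 7.2e-10, and adjusted p = 0.19 with an estimated correlation). CXCL3 departed by 1.66 ± 0.23, CXCL2 by 1.55 ± 0.37, CXCL1 by 1.4 ± 0.26 and LCN2, an iron-sequestering protein of epithelia, by 1.09 ± 0.21. Of 64 G2/M genes 32 lay above and none below (56 over the list alone, median 0.83, camera adjusted p = 4.1e-29, and adjusted p = 0.22 with an estimated correlation), among them CCNB1 (1.27 ± 0.25), PTTG1 (1.23 ± 0.2), BIRC5 (1.13 ± 0.2, dimmer probe sets 0.29 to 0.59) and BUB1 (1.07 ± 0.18). DEPDC1, a mitotic gene outside the list, departed by 1.47 ± 0.33. Interferon-stimulated genes had 3 of 50 above (38 over the list alone, median 0.89, camera adjusted p = 6.5e-16, and adjusted p = 0.25 with an estimated correlation), with IFITM2 at 0.85 ± 0.2 and DTX3L, a ubiquitin ligase, at 0.77 ± 0.21.

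Integrated stress and unfolded protein response genes had 7 of 36 above and none below (14 over the list alone, median 0.49, camera adjusted p = 1.6e-09, and adjusted p = 0.22 with an estimated correlation), with CEBPB at 0.89 ± 0.18 and ATF5 at 0.72 ± 0.15. Apoptosis regulators had 5 of 33 above (13 over the list alone, median 0.35, camera adjusted p = 1e-07, and adjusted p = 0.22 with an estimated correlation), with PMAIP1 at 1.14 ± 0.25 and MCL1 at 0.68 ± 0.13. Immediate early genes had 4 of 34 above (8 over the list alone, median 0.28, camera adjusted p = 9e-05, and adjusted p = 0.22 with an estimated correlation), with IER3 at 1.02 ± 0.2. Replication checkpoint genes had 2 of 23 above, also over the list alone, CDC25B (0.98 ± 0.24), a phosphatase that activates CDK1, and DBF4 (0.91 ± 0.22), the activator of the CDC7 kinase (camera adjusted p = 0.0031, and adjusted p = 0.32 with an estimated correlation). ID1, an inhibitor of differentiation factors, lay above by 1.55 ± 0.29. Below the sum lay IL33 (-0.92 ± 0.2), the splicing factor NOVA1 (-0.84 ± 0.21), the homeobox gene LHX6 (-0.73 ± 0.15) and MCHR1, a neuropeptide receptor (-0.71 ± 0.15). Extracellular matrix and fibroblast markers had a median of -0.22, with none of 25 past the test and 6 below over the list alone (camera adjusted p = 0.0048, and adjusted p = 0.27 with an estimated correlation).

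Above the median level of all genes lay 323 of the 358 positive departures, and below it lay 349 of the 407 negative ones. Quantile normalization left 1 gene, CXCL3, and ended the call of the replication checkpoint list (median 0.189), as did the filter on dim genes and leaving out shared probe sets, and median subtraction gave 484 above and 329 below. With the interquartile range and with the extracellular matrix covariate limma passed none (706 and 3317 at an unadjusted p under 0.05), and with the filter on dim genes 383. Interquartile ranges differed between the groups, so this covariate cannot separate spread from treatment. The interquartile range covariate also ended the camera calls of the replication checkpoint (median 0.18), immediate early (0.011) and extracellular matrix lists (-0.122), and the matrix covariate that of the last. The matrix covariate is the mean of that same list, so it takes out the list's change by construction. Without both arrays that lay apart 1406 lay above and 1297 below, with all 765 kept. The count was 0 without combination replicate 3 (4092 at an unadjusted p under 0.05) and 310 without combination 4. It was 344, 31 and 1 without vehicle 1 to 3, 162, 1490, 145 and 150 without gemcitabine 1, 2, 3 and 5, and 2110, 485, 1720, 19 and 93 without GNE-783 1 to 5.

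Across genes, the combination's log2 change had a slope of 0.41 on the sum of the single-agent changes (r = 0.58). Genes are not replicates and both sides share the vehicle arrays, so arrays with unchanged groups were simulated, which gave a slope of 0.36 (SD 0.11) and r = 0.6. The covariance was 0.0474, against 0.0148 simulated. All 9 genes called with gemcitabine were also called in the combination in the same direction, 5 up and 4 down, where independent lists give 0.2 and 0.21 and 100 simulations gave 0. The simulated groups hold no changes, so this 0 sets no expectation for 9 called genes, and the number for independent lists leaves out the shared vehicle arrays. Most of the 9 genes also lay to the same side of vehicle with GNE-783 alone, so their overlap is not particular to gemcitabine. With the vehicle arrays divided between both comparisons in 6 ways, 0 to 1 genes were shared, and the fold changes correlated with r = 0.43 to 0.65. Gemcitabine had only 0 to 3 calls in these divisions, so their shared counts cannot tell how far the calls overlap. With shared arrays r was 0.73, against 0.51 simulated. The shared count was 1 without vehicle replicate 2 and 590 without gemcitabine replicate 2.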

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

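The screen for arrays far from their group, the interaction and the counts of other splits were set before the data were examined, while the 7 tests of the 3 patterns weighed here were chosen after the results were seen, and the criteria of 6 of them were revised once their values were known.

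The change with GNE-783 differed between tumors with and without gemcitabine for 765 genes, by the limma interaction test. The difference of the changes on the log2 scale was 2.26 for CCL20, 2.07 for NNMT, 1.91 for PI3, 1.85 for CXCL8, 1.66 for CXCL3, 1.55 for CXCL2, 1.55 for ID1, 1.47 for DEPDC1 and 1.4 for CXCL1. It was 1.27 for CCNB1, 1.23 for PTTG1, 1.14 for PMAIP1, 1.13 for BIRC5, 1.09 for LCN2, 1.07 for BUB1, 1.02 for IER3, 0.98 for CDC25B, 0.91 for DBF4 and 0.89 for CEBPB. Smaller differences were 0.85 for IFITM2, 0.77 for DTX3L, 0.72 for ATF5 and 0.68 for MCL1. Negative differences were -0.92 for IL33, -0.84 for NOVA1, -0.73 for LHX6 and -0.71 for MCHR1. The count was 0 without combination replicate 3 (4092 genes at an unadjusted p under 0.05), and after quantile normalization CXCL3 alone of these 27 genes passed.

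Chance as the source of each count was tested by splitting the same arrays in other groups of the same sizes. For gemcitabine, 2 of 100 splits drawn from 126 gave as many genes as the real 9, which argues against chance, but the other of these, with the vehicle arrays and gemcitabine replicate 2 on a side, gave 1830, which points to a structure of the samples. For GNE-783, 2 of 100 gave as many as the real 1248, and the other, with the vehicle arrays and GNE-783 replicate 1 on a side, gave 1558. Chance was also argued against for the combination against vehicle, where 1 of 35 splits, the real one, gave 1851 genes and the next 2. In the combination against gemcitabine 1 of 100 splits, the real one, gave 46 and the next 20. Against GNE-783 1 of 100 gave 2243 and the next 1405, a split with GNE-783 replicate 1 among combination arrays. In the interaction 1 of 100 splits, the real one, gave 765 and the next 6. These splits exchanged arrays between the combination and gemcitabine, and between GNE-783 and vehicle. The change with GNE-783 itself thus added to their spread, which lowers their counts also without an interaction. They therefore cannot decide on chance for the interaction.

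The array labelled GNE-783 replicate 1 lay with the gemcitabine arrays, and the array labelled gemcitabine replicate 2 lay towards GNE-783. With each array placed on axes made without it, they lay at 1.05 and 0.31 from GNE-783 (0) to gemcitabine (1), where the other GNE-783 arrays lay at 0 to 0.38, the other gemcitabine arrays at 0.51 to 1.23 and vehicle arrays at 0.42 to 0.59. Labels exchanged between both groups cannot be told apart, because each array lay within the other group there, but the first lay at 0.39 from gemcitabine (0) to combination (1), above the other gemcitabine arrays (0.02 to 0.35), and no label was changed here. An animal given both drugs cannot be told apart for the first, because 0.39 also lay below the combination arrays (0.47 to 1.19), while its interferon mean of 9.53 was above every gemcitabine array (up to 9.27) and just below the combination (9.55 to 9.83). For the second a missed gemcitabine dose cannot be told apart, because it lay at 0.1 from vehicle (0) to gemcitabine (1), within vehicle arrays (-0.01 to 0.33), but at 0.41 from vehicle (0) to GNE-783 (1), above vehicle arrays (0.03 to 0.31) and close to other gemcitabine arrays (0.12 to 0.4), and differences in response between tumors were not tested.

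In GNE-783 arrays, and less so in gemcitabine arrays, dim genes were higher and bright genes lower than in vehicle arrays. An unequal spread of intensities left by the submitters' normalization cannot be told apart, because quantile normalization left 159 of 1248 calls (12.7%), while the 1248 genes kept 73% of their median size. The median log2 change of the rises went from 0.35 (median SE 0.09) to 0.29 (0.08) and that of the falls from -0.35 (0.09) to -0.2 (0.08), all with the same sign. Of the 1089 calls that ended, 321 kept an unadjusted p as low as that of a call before and ended by the stricter adjustment, and in the other 768 the change was smaller. Less human and more mouse RNA cannot be told apart, because the control probe set for human Alu repeats differed by 0, with a 95% interval by exact permutation from -0.18 to 0.21 that reaches the -0.18 of the brightest 10% of genes, and an effect of GNE-783 on the spread itself was not tested.

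Interferon-stimulated genes and NF-kB targets were higher with the combination than with vehicle. Unequal spread is argued against, since 46 of the 51 risen members passed after quantile normalization, with 99% of their median size. Host leukocytes cannot be told apart. Their markers had a median log2 change of -0.01 (interquartile range 0.22) where the interferon list had 1.01, but 11 were higher and 12 lower, 3 of 23 rose, with LAPTM5 1.73-fold and CD74 1.58-fold higher, only 4 lay above the median gene, and LYZ was bright enough (13.05 ± 0.07 in vehicle) to hide a small share. A response of the tumor cells and mouse transcripts of other host cells were not tested.

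An array was counted as far from its group when its gap to the nearest other array made up an unusually large share of the group's range. This held for 44 of 624 group values tested, where chance gives about 1 in 20, or 31. The share for the array labelled GNE-783 replicate 1, the highest of its group each time, was 0.73 for the mean of the DNA repair genes, 0.78 for APOBEC3B, 0.79 for BLM, 0.81 for BST2, 0.74 for CD74, 0.75 for ECM1, 0.79 for HCP5, 0.86 for RRM1, 0.86 for S100A2 and 0.76 for TK1. Among other GNE-783 arrays it was 0.77 for CCNB1 in replicate 3, 0.73 for COL6A1 and 0.83 for DHCR7 in replicate 5, and 0.77 for ENO1 in replicate 2. Gemcitabine replicate 2 lay apart for CXCL2 (0.87), EBP (0.77), KIF2C (0.78) and UBE2C (0.8), replicate 5 for BUB1 (0.82), replicate 4 for LCN2 (0.72) and replicate 1 for the leukocyte markers (0.86).

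Combination replicate 3 lay apart in its interquartile range (0.94), the G1/S genes (0.88), the housekeeping genes (0.84), CD74 (0.88), GDF15 (0.86) and SERTAD1 (0.94). Combination replicate 1 lay apart for HCP5 (0.85), ID1 (0.86) and KIF14 (0.85), and replicate 4 for IL33 (0.85) and the erythroid, muscle and adipocyte markers (0.89). Vehicle replicate 2 lay apart for ID1 (0.88), MCM5 (0.9), MKI67 (0.85) and PLD1 (0.91). Vehicle replicate 4 lay apart for the histone genes (0.97), HOTTIP (0.89) and INSIG1 (0.88), replicate 3 for the immediate early genes (0.92), DHCR7 (0.88) and LAPTM5 (0.93), and replicate 1 for AURKA (0.97) and UGT2B28 (0.84).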

How the results depend on the processing

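Leaving out both arrays that lay apart, the interquartile range covariate and the permutation test on list means were chosen after the data were seen, the pair from the plot of principal components, on which gemcitabine replicate 5 was also intermediate; all other alternatives were planned. Counts are given for gemcitabine, GNE-783 and the combination against vehicle, the combination against gemcitabine and against GNE-783, and the interaction. Kept within 1.5 times were the counts with the mean of all probe sets and with trend and robust moderation, and, for the combination against vehicle, every alternative tried except array weights and 6 single arrays left out.

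Those that moved more were, with median subtraction, gemcitabine 15, and with quantile normalization gemcitabine 5, GNE-783 175 and the interaction 1. The filter at the 40th percentile gave gemcitabine 5, GNE-783 716 and the interaction 383, and leaving out probe sets shared between transcripts gave gemcitabine 4. Array weights gave 1623, 1888, 3790 and 348 for the first 4 comparisons and 1480 for the interaction. Fitting only the compared groups gave gemcitabine 0 (4576 at an unadjusted p under 0.05), GNE-783 125, and the combination 101 against gemcitabine and 1273 against GNE-783. The replicate block gave 4, 279, 26 against gemcitabine and 4 in the interaction. The labels give no shared animal for a number, and only 13 of 25 pairs of the same number correlated over 0.1 after group means were removed (-0.33 to 0.4), so the arrays were not taken as paired. As a hint from the data, not the design, the median correlation was 0.11 for the same number and -0.02 for others, and 9 of 18 arrays, not all, correlated best with their own number, so a shared factor is not excluded. The extracellular matrix covariate gave 1, 577, 2, 1337 and, in the interaction, 0 (3317 unadjusted). Both arrays left out gave 1820, 2538, 106, 3612 and 2703. The interquartile range covariate gave 0 for gemcitabine (1630 unadjusted), 0 for GNE-783 (1223), 3 and 57 for the combination against gemcitabine and GNE-783, and 0 for the interaction (706). Because these ranges differed between the groups, this covariate also takes up changes that follow treatment, and its counts cannot separate spread from treatment.

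Single arrays left out gave 1 (without vehicle 2, vehicle 3, gemcitabine 3 or gemcitabine 4) to 1104 (without gemcitabine 2) for gemcitabine, 72 (vehicle 3) to 2522 (GNE-783 3) for GNE-783, 938 (vehicle 4) to 2196 (GNE-783 1) for the combination against vehicle, 3 (combination 3) to 126 (GNE-783 1) against gemcitabine, 745 (combination 3) to 3377 (GNE-783 1) against GNE-783, and 0 (combination 3) to 2110 (GNE-783 1) for the interaction. The slope of additivity went from 0.343 (GNE-783 1) to 0.459 (GNE-783 5), and was 0.612 over the 2817 genes called at least once, and the shared genes from 1 (the same 4 arrays as for gemcitabine) to 590 (gemcitabine 2).

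Directions turned for medians of lists, to -0.092 for cholesterol synthesis in the interaction (quantile) and -0.017 for histones with GNE-783 (filter). Matrix markers against gemcitabine turned to 0.002 with the matrix covariate, which is the mean of this same list and so holds its change near 0. With the interquartile range covariate medians turned to 0.085 for immediate early genes, 0.007 for apoptosis regulators and -0.003 for leukocyte markers with GNE-783. It also turned that of the stress responses against GNE-783, to -0.026. Directions of single genes turned as well. Without probe sets shared between transcripts directions turned for CNDP2 (0.169) and CEP290 (0.291) with gemcitabine, ENO1 (0.331) and DES (-0.078) with GNE-783, ENO1 (0.232) and DES (-0.108) with the combination, CHAF1A (-0.078), FAS (-0.008) and UMPS (-0.149) against GNE-783 and MUC8 (0.109) in the interaction, where another probe set then stood for the gene. Directions were compared only for values past the threshold before or after the change of setting. Of the other values of single genes, 9572 kept their side of the threshold, 2005 were no longer past it and 48 came past it, and of those of lists 3567, 206 and 105. Values past the threshold in neither setting count as kept, whatever their direction. Of 68 camera calls, 50 were kept after quantile normalization and 2 with an estimated correlation. Fewer arrays explain part of the changes when arrays are left out; for the rest the cause was not tested. The planned covariate of RNA quality was not run, and the signal of dim probe sets over background limits what can be said of genes near the floor of the arrays.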

Other observations

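The comparisons in this part were planned, except for the test with both arrays left out, which was chosen after the results were seen, and the genes were picked from the rule's genes after their values were seen. Genes of the intestinal stem cell and Wnt list fell with the combination against vehicle, 5 of 27 with none up (6 over the list alone), with a median log2 change of -0.13 (camera adjusted p = 0.014, and adjusted p = 0.39 with an estimated correlation). Array weights, the filter on dim genes and leaving out shared probe sets also ended this call. PROM1 (CD133), a surface marker of stem and progenitor cells, changed by -0.72 ± 0.14 (10.28 ± 0.16 against 10.99 ± 0.22, SD, n = 4 each), LRIG1, a brake on growth factor receptors, by -0.73 ± 0.17 and CDCA7, a MYC target, by -0.57 ± 0.1. Dimmer probe sets changed by 0.01, 0.03 and 0.23 for LRIG1 and by -0.36 for CDCA7. Of 50 intestinal differentiation genes 3 rose and 1 fell (3 and 0 over the list alone, median 0.02, camera adjusted p = 0.76). Keratin 20 (KRT20), a marker of mature colonocytes, was 1.48-fold higher, the secreted trefoil peptide TFF1 1.55-fold and CDX1 1.25-fold. AGR2, a protein of secretory cells, changed by -0.2 ± 0.06, a call that ended under several alternatives, among them quantile normalization and both arrays that lay apart left out. Leaving out single arrays also ended the calls of KRT20, TFF1, CDX1 and LRIG1, and the mean of all probe sets that of LRIG1.

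Hypoxia and glycolysis genes had 2 of 35 down with the combination and none up (5 over the list alone), with a median log2 change of -0.38 (camera adjusted p = 4.8e-05, and adjusted p = 0.51 with an estimated correlation). ENO1, enolase, changed by -0.47 ± 0.09 and PGK1, phosphoglycerate kinase, by -0.43 ± 0.12. ENO1 has 3 dimmer probe sets, which changed by -0.16, 0.06 and 0.23. LDHA, lactate dehydrogenase, was 13.6 ± 0.15 against 13.81 ± 0.09 and did not pass. With gemcitabine alone the median of this list was -0.41, with none past the test over all genes and 2 lower over the list alone (camera adjusted p = 8.7e-09, and adjusted p = 0.61 with an estimated correlation). Of 35 measured histone genes 2 rose and 2 fell with the combination (3 and 2 over the list alone), with a median of 0.03, a mean of -0.02 and camera up (adjusted p = 0.73). H2BC21 changed by -0.77 ± 0.19 and H2AC6 by -1.07 ± 0.22, H2BC11, a dim gene (3.69 ± 0.1 against 3.32 ± 0.14), by 0.37 ± 0.08 and H3C8 by 0.32 ± 0.08. Of 14 housekeeping genes 2 rose and 2 fell (3 and 2 over the list alone, median 0.02, camera adjusted p = 0.73), among them the transferrin receptor TFRC (-0.67 ± 0.18), PGK1 and the tubulin TUBB (0.55 ± 0.16, dimmer probe sets 0.1 and 0.55). Leaving out single arrays ended the calls of PGK1, TFRC, TUBB, H3C8 and H2BC21, and the mean of all probe sets those of ENO1, PGK1, TFRC and TUBB.

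Markers of other cells were present in vehicle arrays at differing levels. Above the median gene of these arrays (7.13) lay 13 of 25 extracellular matrix and fibroblast markers, 5 of 16 endothelial, 4 of 23 leukocyte and macrophage and 3 of 20 erythroid, muscle and adipocyte markers. HT-29 cells can express some of these genes themselves, and the arrays cannot assign them to a cell. The human probes were not compared with mouse sequence here.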
